A study of Mus musculus with 4 samples.

How the data were processed

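Liver RNA from mice with a nonfunctional Wrn helicase domain that had received resveratrol was hybridised with liver RNA from untreated wild-type mice on 4 two-colour arrays. The labels give total RNA, a labelling protocol from Agilent, male C57Bl/6 animals aged 9 months, food without restriction and a reversed light-dark cycle. Channel 1 held wild-type animal 2 on arrays 1 and 3 and wild-type animal 4 on arrays 2 and 4. Channel 2 held a different mutant on each array. The mutant carried Cy5 on arrays 1 and 2 and Cy3 on arrays 3 and 4, so a dye effect on a gene cancels in the mean of the 4 arrays when all ratios run the same biological way. The 4 arrays formed 1 group, with the mutant number as replicate number.

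The values analysed were the log2 ratios that the authors deposited, 1 per probe and array. The log base is not stated in words: limma, which the submitters' processing notes name without a version, works in log2, and the extremes of -8.54 and 7.54 would exceed a scanner's range on a log10 scale. The values do not exclude a natural log, on which the folds would be larger than printed. Background correction, normalization within arrays, filters and the direction of the ratios are not given in the sources used here. The table held 43379 probes per array with 0 missing values, and the medians of arrays 1 to 4 were 0.01, 0.01, -0.01 and -0.01. Signal intensities were not used here, so it was not possible to say which probes lay above background, and a fold for a gene that is silent on one side is a measured ratio and no bound. The number of arrays limits the precision.

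A rule fixed before the data were examined was to settle the direction of arrays 3 and 4 from correlations over all probes. It compared array pairs of opposite dyes that shared a wild-type animal (mean r = -0.03) with pairs of opposite dyes and different wild-type animals (mean r = 0.02), and, as its second criterion, took the mean over all opposite-dye pairs (r = -0.01). Both criteria read the values as Cy5 over Cy3 and called for turning arrays 3 and 4. The rule was set aside, and the values were used as deposited, after the data had been seen in the orientation as deposited, gene list means and Xist included. This departure changes the main result, because turning arrays 3 and 4 gives 0 genes past the threshold.

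The reasons for the departure were these. The value table's order follows an array layout with 85 columns, in which a running median over 11 x 11 spots held 34.1%, 19.8%, 21.8% and 12.2% of the variance of arrays 1 to 4. That trend correlated at a mean r of 0.17 between arrays of the same dyes and -0.32 between arrays of opposite dyes, as a trend tied to a dye does in ratios that have already been turned. With the trend subtracted, the mean r of the opposite-dye pairs was 0.10 (Pearson; Spearman's rho was 0.02, with arrays 1 and 3 at -0.04), and the shared-minus-different contrast moved from -0.05 to 0.01, too small to decide by itself. Of the probes, 200 were over 1 in size with one sign on all 4 arrays as deposited, against 32 with arrays 3 and 4 turned and 1 in each of the other pairings. These counts are themselves part of the outcome and are not independent of it. Xist, the RNA that coats the inactive X chromosome, had a negative mean over its probes on every array, although 1 probe stood at 0.25 on array 3. With arrays 3 and 4 turned, and without a dye effect on Xist, wild-type animal 2 would lie far above mutant 1 and far below mutant 3 in that mean. If the value shared by the arrays were a dye effect, no such difference between animals would follow. Xist therefore does not decide the orientation by itself. The absolute direction, mutant over wild type, is called likely because the series title and the order of the channels agree on it. It was not settled by the dyes.

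Gene symbols came from the platform annotation: 33653 probes had 1 gene symbol, 56 had several and 9670 had none. The Entrez IDs of 33517 probes matched the reference gene table, and 0 symbols needed an update. The log2 ratios of all probes whose only symbol was the same were averaged, which gave 19087 genes, 8343 of them with 2 or more probes. Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit with an intercept only, eBayes with its default prior, two-sided test against 0) and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. The prior had 3.63 degrees of freedom. The 36 gene lists (25 of pathways or functions and 11 of cell types) were written before the data were examined, and each with at least 5 measured members was tested with camera at its preset inter-gene correlation of 0.01, again with a correlation estimated for each list, and with fry, adjusted over the 36 lists. With an estimated correlation, camera also tests against the few residual degrees of freedom of the arrays, so its p-values rise for that reason too. Members were counted with the adjustment over all genes and adjusted over the list alone. A fit with a dye coefficient counted genes whose ratio depended on the dye. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables, running medians and plots.

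Genes were named by a rule fixed before the data were examined: Wrn, then the 12 highest and 12 lowest mean log2 ratios among genes past the threshold with 1 sign on all 4 arrays, skipping predicted genes and clones, then up to 4 members of each list whose shift passed and up to 2 of each other list, by smallest p. Other genes that are named were chosen after their values were seen. Several named genes belong to families of close paralogs whose RNA may hybridise with each other's probes, among them the Cyp4a, Cyp2b, Cyp3a, Gstp, Mt and Ces3 families, and their single values are uncertain for that reason.

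The steps were tested on simulated data with 19087 genes on 4 arrays and the variance of the real table. Of 50 genes simulated at each log2 size, 6% were called at a size of 1, 82% at 2, 92% at 3 and 98% at 4, with 8 false calls. The wild-type side holds 2 animals, so the 4 ratios are not fully independent. Where 50% of the simulated noise came from the shared wild-type animal, 12.6% of unchanged genes had an unadjusted p under 0.05, against 5.22% with independent arrays, and 0 passed the adjusted threshold. In the real table the consensus correlation within a wild-type animal was -0.37, opposite in sign to that simulation. The arrays of each wild-type animal have opposite dyes, so dye effects also enter this value.

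Alternatives planned before the data were examined were each array left out, the wild-type animal as a random block, its arrays averaged, a dye coefficient, centring, scaling, arrays 3 and 4 turned, other rules for probes, tests, thresholds and filters, and other list tests. Subtraction of the spatial trend was added after the data had been seen.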

Results

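Gene expression in mouse liver was measured on 4 two-colour arrays, on which 2 RNA samples carrying different dyes compete for the same probes. Each array set a resveratrol-treated mouse with a nonfunctional helicase domain of Wrn, the RecQ helicase that is mutated in the premature ageing disorder Werner syndrome, against an untreated wild-type mouse. Resveratrol is a plant polyphenol. The 4 mutants were different animals, whereas the wild-type side held 2 animals, each used on 2 arrays of opposite dye. The comparison asks which liver genes differed between treated mutants and untreated wild types. Genotype and treatment differed together, and untreated mutants or treated wild types were not analysed here. Ratios of 43379 probes gave values for 19087 genes, and the SD of the log2 ratios over probes was 0.80, 0.73, 0.90 and 0.66 on arrays 1 to 4.

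Log2 ratios are given as deposited, and a positive value is likely mutant over wild type. The series title and channel order are the basis for that direction, and higher and lower would exchange if it were the opposite. Whether arrays 3 and 4 run the same way as arrays 1 and 2 was also not stated. The rule fixed before the data were examined called for turning arrays 3 and 4, and it was set aside after the data had been seen. With those arrays turned, 0 genes passed limma's adjusted threshold (1518 had an unadjusted p under 0.05), and the values shared by the 4 arrays would be effects of the dyes. Every result that follows depends on this choice.

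Wrn itself had a mean log2 ratio of 0.12 ± 0.73 (SD, n = 4 arrays) and was above 0 on 2 of 4 arrays. Its 4 probes disagreed in sign, from -0.50 to 0.57, and whether they lie in the deleted part of the gene is not given in the sources used here, so they check no label.

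In the orientation as deposited, 47 genes changed, 15 higher and 32 lower in the treated mutants, and all 47 had one sign on all 4 arrays. The genes with the highest ratios were Srebf1, which encodes the transcription factor that drives fatty acid synthesis genes, at 3.72 ± 0.62, Elovl3, a fatty acid elongase, at 3.65 ± 1.10, and the glutathione transferase gene Gstp1 at 3.62 ± 0.39 (SD, n = 4 arrays). The metallothionein gene Mt2, whose product binds zinc and copper, was lowest at -6.14 ± 0.99, or 70.4-fold lower, and Mt1 fell with it to -4.58 ± 1.42, although the means of its 11 probes ran from -6.12 to -0.0217. Cyp4a14, a fatty acid hydroxylase, was 52.0-fold lower at -5.70 ± 2.03, a fold that depends on the arrays, which ran from -3.03 on array 1 to -7.67 on array 3. The other genes among the 12 highest were C8a at 3.27, Nat8 at 3.26, Nudt7 at 2.92, Ces3b at 2.75, Fasn at 2.74, Cyp2c70 at 2.67, Alas2 at 2.45, Pklr at 2.00 and Inmt at 1.97. The other genes among the 12 lowest were A1bg at -4.94, Cyp17a1 at -4.76, Cyp4a31 at -4.26, Cyp4a10 at -4.23, Igfbp1 at -4.18, Cyp2b13 at -4.04, Ehhadh at -3.64, Sult3a1 at -3.58 and Cidec at -2.83.

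**Figure D1:**
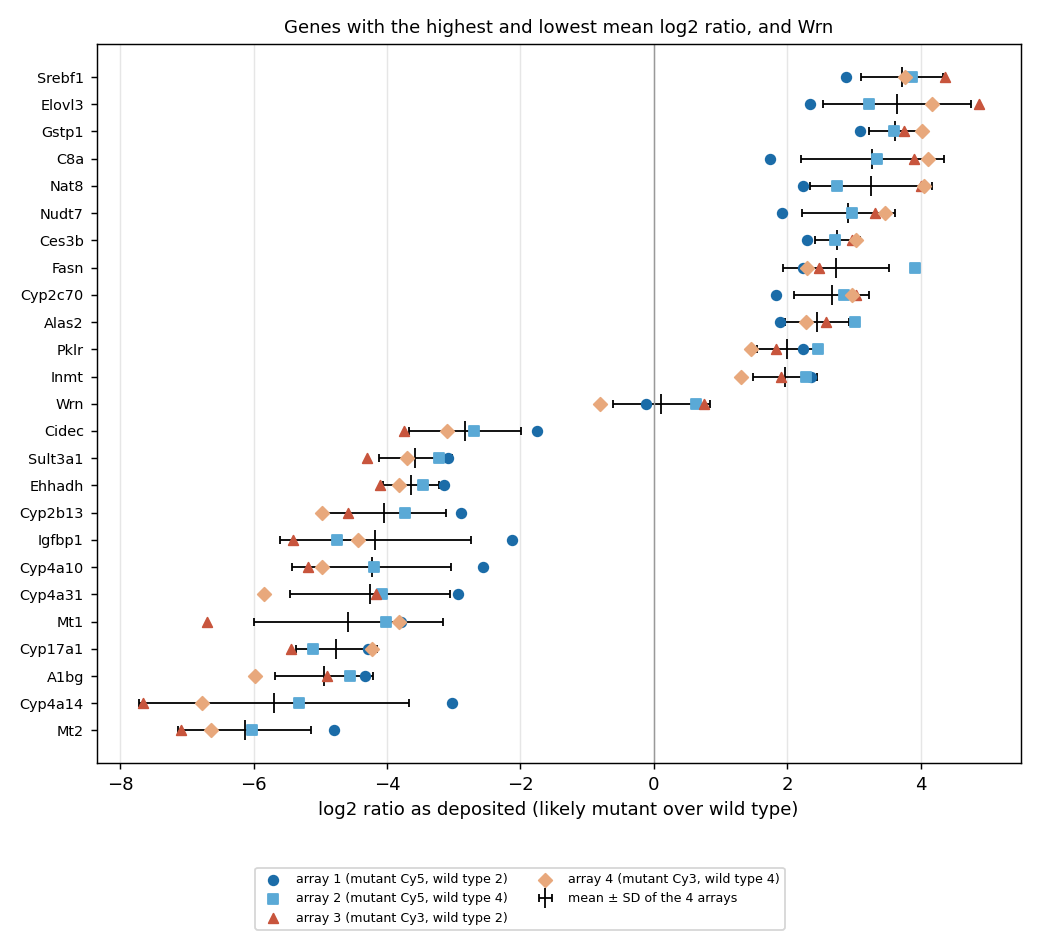
Log2 ratios of Wrn and of the 12 highest and 12 lowest genes past the threshold (horizontal axis, as deposited, likely mutant over wild type), with 1 symbol per array and the mean ± SD of the 4 arrays in black. All 24 genes lay on one side of 0 on the 4 arrays, and Wrn lay on both sides.

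Adjusted p-values of the 47 genes ran from 0.00509 to 0.0476. At an unadjusted p under 0.05 there were 1268 genes, against 954 expected by chance with independent arrays. The wild-type animals are shared, and 12.6% of unchanged genes had such a p in a simulation in which they gave 50% of the noise. The simulated arrays of a wild-type animal were positively correlated, whereas the consensus correlation in the data was -0.37. The arrays of each wild-type animal also carry opposite dyes, so dye effects enter that correlation. A value below 0 therefore does not show that the shared animals left the arrays independent. How far the simulation describes these arrays, and whether 1268 is an excess, stays undecided. The count fell when an array was left out, which also lowers the degrees of freedom. Then 34 genes passed without array 1, 0 without array 2 (940 at an unadjusted p under 0.05), 9 without array 3 and 0 without array 4 (926). Scaling the arrays to the same spread gave 15 genes, 13 of them among the 47. The wild-type animal as a random block, with its consensus correlation of -0.37, gave 194. Subtracting the spatial trend on the arrays, an alternative added after the data had been seen, gave 122.

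Genes that are more active in female than in male mouse liver were lower as a set, and genes more active in male liver were higher, although the labels give all animals as male. Of 19 female-predominant genes measured, 4 fell, 0 rose and 15 did not pass, with 14 lower when adjusted over the list alone. Cyp17a1, a steroid hydroxylase, was 27.1-fold lower at -4.76 ± 0.61, A1bg was 30.8-fold lower at -4.94 ± 0.73, and the sulfotransferase gene Sult3a1 and the cytochrome P450 gene Cyp2b13 were 11.9-fold and 16.5-fold lower (n = 4 arrays). The list mean was -2.03 to -1.76 on arrays 1, 2 and 4 and -2.54 on array 3. Of 13 male-predominant genes measured, 3 rose (Elovl3, C8a and Nudt7), 0 fell and 10 did not pass, with 11 higher when adjusted over the list alone. All 13 had a mean above 0, among them Selenbp2 at 2.42 ± 0.87, and the list mean was 0.96 on array 1 and 2.27, 3.04 and 2.78 on arrays 2 to 4. Xist, the RNA that coats the inactive X chromosome in female cells, fell to -2.05 ± 0.46 (adjusted p = 0.0400) and was named after its value was seen. camera gave adjusted p = 1.11e-23 for the female-predominant and 4.47e-20 for the male-predominant list, and these became adjusted p = 0.136 and 0.282 with an estimated correlation.

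Genes of fatty acid oxidation and targets of PPARA, the nuclear receptor that switches them on in fasting, were lower as a set, with a list mean of -1.85 ± 0.54 (SD, n = 4 arrays). Of 32 measured members, 10 fell, 0 rose and 22 did not pass, with 26 lower when adjusted over the list alone, and 0 of the 32 had a mean above 0. Ehhadh, an enzyme of peroxisomal beta-oxidation, was 12.4-fold lower at -3.64 ± 0.42. The thioesterase gene Acot4 stood at -2.56 ± 0.24, Angptl4, whose product inhibits lipoprotein lipase, at -2.80 ± 0.64, and Cyp4a31 at -4.26 ± 1.20. The 3 probes of Cyp4a10 had means from -6.09 to -2.53. Cpt1a, the gate for fatty acid entry into mitochondria, fell to -1.76 ± 0.23 and the acyl-CoA dehydrogenase gene Acadm to -1.81 ± 0.31. camera gave adjusted p = 4.04e-44, and adjusted p = 0.282 with an estimated correlation.

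Genes of lipogenesis and of cholesterol synthesis were higher as sets. Of 22 measured lipogenesis genes, 3 rose and 1 fell, and 18 did not pass. When adjusted over the list alone, 8 were higher and 2 lower. Srebf1, Fasn (fatty acid synthase) at 2.74 ± 0.80 and the pyruvate kinase gene Pklr at 2.00 ± 0.45 rose, while Cidec, which encodes a lipid droplet protein and was placed in this list, fell to -2.83 ± 0.84. The 2 probes of Fasn differed, with means of 1.45 and 4.02. Of 19 measured cholesterol genes, 1 rose, 0 fell and 18 did not pass, with 15 higher when adjusted over the list alone. Dhcr7, the last enzyme of one branch of cholesterol synthesis, rose to 1.94 ± 0.28, and Insig1, Sc5d and Pmvk had values of 2.77 ± 0.90, 1.57 ± 0.30 and 1.17 ± 0.22 (n = 4 arrays). camera gave adjusted p = 5.77e-05 for lipogenesis and 2.44e-19 for cholesterol synthesis, and both had adjusted p = 0.328 with an estimated correlation.

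**Figure D2:**
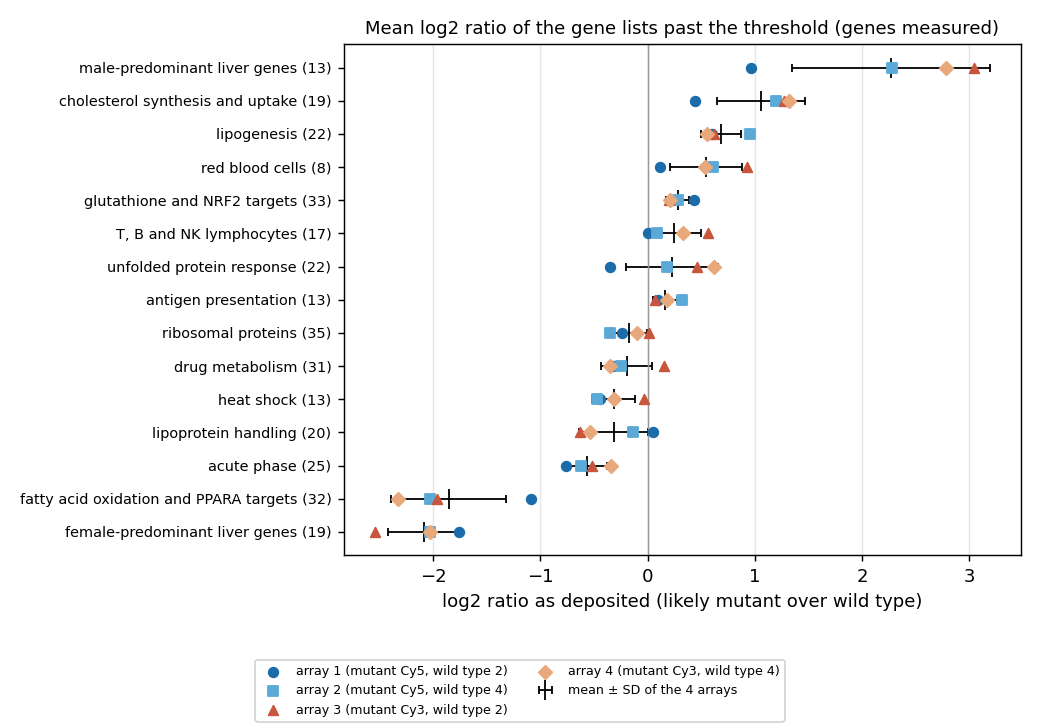
Mean log2 ratio over the measured members of the 15 gene lists past camera's threshold (horizontal axis, as deposited, likely mutant over wild type), with 1 symbol per array and the mean ± SD of the 4 arrays in black. The numbers of measured genes stand in parentheses. Array 1 lies nearest to 0 for the male-predominant, female-predominant, cholesterol, PPARA, red blood cell, lymphocyte and lipoprotein handling lists.

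The glutathione and NRF2 list was higher by a mean of 0.28 ± 0.11, with 1 of 33 measured members rising (Gstp1) and 0 falling. Gstm6 at 1.51, Gsta3 at 1.23 and Gstm3 at 1.29, which encode other glutathione transferases, did not pass. The acute phase list was lower at -0.56 ± 0.18, and the 2 of its 25 members that fell were Mt1 and Mt2. Its median member was at -0.13 and 11 of the 25 lay above 0. Lbp stood at -0.97 and Hamp2 at -1.92. Drug metabolism genes were lower at -0.20 ± 0.24, although the member that rose was Cyp2c70, and Cyp3a11 at -1.46, Sult1a1 at -0.89 and Nr1i3 at -1.42 did not pass. The mean of the drug metabolism list was 0.15 on array 3 and below 0 on the other arrays. camera's adjusted p for these lists was 0.0253, 0.0419 and 0.0117, and adjusted p = 0.504, 0.506 and 0.506 with an estimated correlation. Without array 1 none of the 3 calls held (adjusted p = 0.349, 0.637 and 0.128), and the acute phase call was also lost without array 2 (0.131) and the drug metabolism call without array 4 (0.0633).

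Further lists passed camera with small mean shifts and with 0 members past the threshold. Heat shock genes, which encode chaperones, were lower at -0.32 ± 0.20 (Hsp90aa1 at -0.85, Hspd1 at -0.62, Hspb1 at -0.67, Hsph1 at -0.85). Ribosomal protein genes were lower at -0.17 ± 0.16 (Rps14 at -0.64, Rpl23 at -0.80), and lipoprotein handling genes at -0.32 ± 0.32 (Apoa4 at -2.54, Lcat at -0.79, Apoa5 at -0.74, Mttp at -1.32). Unfolded protein response genes were higher at 0.23 ± 0.43 and antigen presentation genes at 0.16 ± 0.11 (SD, n = 4 arrays), with Sdf2l1 at 1.12 and H2-DMa at 0.47. The array means of the unfolded protein response list were on both sides of 0, from -0.35 to 0.62. Those of the ribosomal protein list also reached 0.0094 on array 3, and those of the lipoprotein handling list 0.046 on array 1. Adjusted p-values were 0.000691 for heat shock, 0.00603 for ribosomal proteins, 0.0435 for lipoprotein handling, 0.0108 for the unfolded protein response and 0.0355 for antigen presentation. The corresponding values were adjusted p = 0.328, 0.506, 0.582, 0.782 and 0.506 with an estimated correlation. Of these calls, ribosomal proteins was lost without array 2 (adjusted p = 0.1998), lipoprotein handling without array 3 or 4 (0.268 and 0.304), the unfolded protein response without array 3 or 4 (0.246 and 0.388) and antigen presentation without array 2, 3 or 4 (0.161, 0.0702 and 0.0932).

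Among markers of other cell types, those of red blood cells were higher at 0.55 ± 0.33, with 1 of 8 measured members rising, the heme synthesis gene Alas2 at 2.45 ± 0.48. Hba-a1 stood at 1.03, Hbb-bt at 0.65 and Car2 at -1.35. Lymphocyte markers were higher at 0.25 ± 0.25 with 0 of 17 members past the threshold, among them Ighm at 0.57, whose probes disagreed in sign, and Cd79b at 0.45. camera gave adjusted p = 0.00374 and 0.0136 for these lists, and adjusted p = 0.504 and 0.485 with an estimated correlation. Without array 3 neither call held (adjusted p = 0.0509 and 0.152), and the lymphocyte call was also lost without array 4 (0.0813). Shifts of the other cell type lists did not pass: hepatocytes had a mean of 0.02 (Ass1 at 1.19, Ttr at 0.97), Kupffer cells 0.02 (Cd5l at 0.44), endothelial cells -0.19 (Egfl7 at -0.71), stellate cells -0.01 (Colec11 at -0.53), bile duct cells -0.01 (Cdh1 at 0.72), neutrophils -0.13 (Lcn2 at -1.34), pancreatic acinar cells 0.04 and skeletal muscle -0.01. Adipocyte markers had a mean of 0.16, and 1 of 10 measured, the lipid droplet gene Plin4, fell to -2.02 ± 0.53.

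The remaining pathway lists did not pass. Gluconeogenesis and glycogen genes had a mean of -0.25, with 1 of 15 falling, Igfbp1, whose transcription insulin represses, at -4.18 ± 1.43, and Pck1 at -1.54 ± 0.36 not past the threshold. Among p53 targets, at a mean of -0.29, the cell cycle inhibitor Cdkn1a fell to -2.44 ± 0.43, with means of its 10 probes from -3.82 to -1.30. List means were -0.11 for insulin signalling (Grb14 at -0.53), -0.09 for sirtuins and mitochondrial biogenesis (Ppargc1a at -0.98), 0.04 for antioxidant enzymes (Glrx at -1.05, Cat at 0.80), 0.02 for oxidative phosphorylation (Sdhb at 0.60) and 0.02 for RECQ helicases and DNA repair (Nbn at -0.37, Ercc2 at 0.35). They were 0.19 for bile acid metabolism (Cyp7b1 at 3.10, Slco1a1 at 3.19), 0.07 for the circadian clock (Nr1d1 at 0.92), 0.08 for cytokines and chemokines (Il18 at 0.60), -0.04 for the interferon response (Bst2 at 0.58) and 0.01 for proliferation (Ccnd1 at -1.19). None of these single genes passed except Igfbp1 and Cdkn1a.

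With a correlation estimated for each list, 0 of the 15 list calls remained. That setting also cuts camera's degrees of freedom to the few that the arrays leave. For the female-predominant list the estimated correlation was 0.048, and camera's unadjusted p went from 6.15e-25 to 0.00377. The loss of calls can therefore not be credited to correlation between genes alone. The estimate was also low for lipogenesis, at 0.065. It was 0.44 for the PPARA list, 0.35 for the male-predominant, 0.54 for the cholesterol and 0.57 for the unfolded protein response list. For those lists the preset of 0.01 lay far below the estimate, so camera's p-values at the preset are likely too small. fry asks another question, whether a list's genes move on balance one way, and does not compare them with other genes. Its directional test passed 2 lists, the PPARA list (adjusted p = 0.0466) and the female-predominant list (adjusted p = 0.0287). In a limma fit with a dye coefficient, 0 genes had a ratio that depended on the dye past the adjusted threshold. At an unadjusted p under 0.05 there were 1683, more than the 954 expected by chance and the 1268 of the main comparison. Dye effects on many genes are therefore not excluded, and the coefficient measures the dye only if the orientation as deposited holds. In that fit 44 genes passed for the mutant over wild-type ratio, 35 of them among the 47.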

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

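All tests of explanations in this part were chosen after the values had been seen, and they hold for the orientation as deposited. A single array stood far from the other 3, relative to the range of the 4, in 9 of 108 named genes and 2 of 36 lists, and chance gives about 1 in 20. These genes were Fasn (3.92 on array 2, others 2.24 to 2.48), Cyp2c70 (1.83 on array 1), Mt1 (-6.70 on array 3, others -4.02 to -3.80), Nr1d1 (-0.0310 on array 4), Apoa5 (-0.45 on array 1), Mttp (-3.04 on array 3), Rps14 (-0.39 on array 4), Colec11 (-0.26 on array 2) and Cxcr6 (1.72 on array 3). The lists were cholesterol synthesis and uptake (0.44 on array 1, others 1.19 to 1.32) and lipogenesis (0.96 on array 2, others 0.55 to 0.62). Among probes without a single gene symbol, which the comparison of genes did not use, 7 passed the threshold when they were added, 5 higher and 2 lower.

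Of the 47 genes past the threshold, 35 had their smallest ratio on array 1, against 4 on each of arrays 2, 3 and 4. The spatial trend does not account for this in the male-predominant list: with the trend subtracted, its mean on array 1 was 1.08, below the 2.21 to 3.10 of the other arrays by more than their SD of 0.45. A common compression of the ratios on array 1 stays open. The slopes of array 1 on the mean of the other arrays ran from 0.32 for the male-predominant to 0.80 for the female-predominant list, and their range of 0.49 over 5 lists was reached by shuffled list membership at a permutation p of 0.0727. These were the 5 lists with the smallest camera p. Array 1 lay farthest from 0 in the glutathione list (0.43, others 0.20 to 0.28) and the acute phase list (-0.77, others -0.62 to -0.34). That is the reverse of a compression, but neither call held without array 1. A difference between mutant 1 and the other mutants also stays open, untested.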

How the results depend on the processing

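Subtraction of the spatial trend and the alternatives to the orientation rule were added after the data had been seen. The orientation decides the result. With arrays 3 and 4 turned, as the rule fixed beforehand asked, 0 genes and 1 list passed (the unfolded protein response, lower, adjusted p = 0.00114), and by construction values shared by the 4 arrays cancelled. Values are given for those that changed sign there; the other 5 called genes and 7 called lists kept their direction and did not pass. List means there were -0.24 for cholesterol synthesis and uptake, 0.30 for PPARA targets, 0.20 for female-predominant, -0.65 for male-predominant, 0.27 for lipoprotein handling, -0.18 for red blood cells, -0.20 for lymphocytes and -0.31 for the unfolded protein response. Log2 ratios there were -0.34 for Srebf1, -0.87 for Elovl3, -0.27 for Gstp1, -0.73 for C8a, -0.77 for Nat8, -0.47 for Nudt7, -0.24 for Ces3b, -0.33 for Cyp2c70 and -0.24 for Dhcr7. They were 0.73 for Mt2, 1.53 for Cyp4a14, 0.50 for A1bg, 0.0656 for Cyp17a1, 0.68 for Mt1, 0.75 for Cyp4a31, 0.85 for Cyp4a10, 0.75 for Igfbp1, 0.73 for Cyp2b13, 0.33 for Ehhadh, 0.42 for Sult3a1, 0.60 for Cidec, 0.0639 for Acot4, 0.0921 for Angptl4 and 0.13 for Cdkn1a. The rule's contrast of -0.051 became 0.00697, 0.00597 and -0.00144 with running medians over 7, 11 and 21 spots subtracted, and 0.0184 on gene means with 11. As Spearman's rho it was 0.00371, 0.00461 and 0.00158, and 0.0140 on gene means. The contrast stayed below 0 without subtraction, at -0.0363 on gene means.

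The 47 genes became 0 to 34 when each replicate was left out (34, 0, 9 and 0 without replicates 1 to 4), each on 3 arrays, and why the arrays differ in this was not tested. Other counts, whose cause was not tested, were 194 with the wild-type animal as a random block (consensus correlation -0.37, below 0, so this fit narrows the error and gives no protection against the shared animals), 15 with scaled arrays, 30 with the largest probe and 30 with probes tested alone and counted as genes. With unnamed probes included, the 25 that passed were 18 genes, all among the 47, and 7 unnamed probes. Among the 3026 genes with 1 sign on all arrays, a filter that chooses genes by the outcome, 296 passed. The ordinary test without a shared prior gave 0 (1403 at an unadjusted p under 0.05). Looser thresholds gave 104 at an adjusted p under 0.1 and 932 at an unadjusted p under 0.05 with 1.5-fold. With the spatial trend subtracted, 122 genes passed, 44 of them among the 47, with 114 and 124 for running medians over 7 and 21 spots, 108 with arrays of a wild-type animal averaged, 102 with a dye coefficient, and 98, 16, 35 and 27 without replicates 1 to 4. Averaging the arrays of a wild-type animal, which takes the shared animals into account with 2 values per gene, gave 44 genes (20 higher and 24 lower), 31 of them among the 47, and 3 of the 29 called named genes were lost. Centring gave 50, the median probe 46 and a robust prior 47. The 15 lists that passed camera became 0 with estimated correlations, which also lower the test's degrees of freedom, and 10 to 12 without each replicate. Of the 15, 13 also passed with the random block, the averaged wild-type animal, the dye coefficient or the spatial trend subtracted, and 14 with scaled arrays. For the random block the list test was cameraPR, which was run on the genes' test statistics instead of the ratios, so that count comes from a different procedure. fry, which does not compare a list with other genes, passed 2 lists in its directional and 19 in its mixed test, 11 of the 19 among the 15. Outside the turned orientation, 0 of the 29 called genes and 0 of the 15 called lists changed direction. For the genes this was largely fixed in advance and is no sign of robustness. Each had one sign on all arrays, which leaving out, averaging or scaling arrays cannot reverse. A dye coefficient together with a random block could not be fitted and was not run, and the filter on missing values removed 0 probes. No paired analysis was possible because each array already compares the 2 sides and there is 1 group. Without intensities, it is unknown which of these ratios rest on signal near background.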

Other observations

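Of the 47 genes, 17 stood in no list. Among those that fell were the lipid droplet gene Plin5 at -2.29 ± 0.26, the fatty acid transporter gene Slc27a1 at -1.88 ± 0.26, Abhd2 at -2.31 ± 0.48 and Retsat, a retinol saturase gene, at -2.53 ± 0.65 (SD, n = 4 arrays). The transporter genes Slc22a26 and Slc22a21 fell to -2.71 ± 0.75 and -2.45 ± 0.66. Cyp2f2 and Sult2a8 rose to 1.77 ± 0.23 and 1.56 ± 0.26. These genes were named after their values were seen.

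The tests of explanations in this part were chosen after the values had been seen. They use the orientation as deposited, except for the values with arrays 3 and 4 turned, an alternative planned before. The first pattern was that Xist and female-predominant genes were lower and male-predominant genes higher, in animals all labelled male. The 4 Xist probes had means of -3.69, -1.95, -1.20 and -1.39. Within an array they differed widely, from -5.33 to -0.14 on array 1 and from -3.25 to 0.25 on array 3. A metabolic state of male animals alone predicts no change of Xist, which male cells do not use, and its ratio was -2.05 ± 0.46. That ratio is the observation that raised the question, so it is no separate test, and without intensities the level of Xist is unknown. It says nothing of the sex-dependent genes, for which such a state stays open beside the PPARA list at -1.85 ± 0.54. The spatial trend is argued against by Xist at -2.06 ± 0.38 with the trend subtracted. A dye effect cancels by design in the orientation as deposited. It would be the shared value itself with arrays 3 and 4 turned, where the mean of Xist is -0.18, so it stays open only as far as the orientation does. Animals of opposite sex on the 2 sides may account for the pattern. The Y-linked genes measured (Eif2s3y, Kdm5d and Uty) had a mean of 0.50 ± 0.47 and lay above 0 on 3 of 4 arrays. Eif2s3y, at 0.80, was above 0 on all 4 arrays, whereas Kdm5d at 0.41 and Uty at 0.30 were below 0 on array 3. Without intensities their detection cannot be judged, so this does not decide. Genotype and treatment stay open for the sex-dependent genes, untested.

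The second pattern was that PPARA targets were lower while lipogenic genes were higher. The spatial trend is argued against by the PPARA list, whose mean was -1.86 ± 0.50 with the trend subtracted. A dye effect stays open only as far as the orientation does, as with Xist, and the mean of 0.30 with arrays 3 and 4 turned is small by construction and speaks for neither. A hypothesis is that feeding state differed between the 2 sides, although the labels give food without restriction. It predicts that genes raised by glucocorticoids and cAMP in fasting are lower as well: the median of 12 such genes was -0.58, 10 lay below 0, and the list mean was below 0 on all 4 arrays, with 0 of the 12 past the threshold. The set was not uniform. The 2 above 0 were Tat at 0.18 and Nr4a1 at 0.17, and among the 10 below 0 G6pc stood at only -0.17. Values of several members, Pck1 and Ppargc1a among them, were known when this set was chosen, so the result is consistent with the hypothesis but does not separate it from genotype, treatment or sex.

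Over the 8 sign patterns of the 4 arrays, 1 gave as many as 47 genes, the one as deposited, and the highest count of the others was 0. The others include the pattern that the rule fixed beforehand had called for. The pattern as deposited was adopted after the data had been seen, in part on probes with one sign on all arrays. Its lead is therefore no independent result. The patterns are too few for a share under 0.05.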
